A study of Rattus norvegicus with 18 samples.

How the data were processed

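Total RNA of liver from 18 male F344 rats, bought at 5 weeks of age, was labelled with Cy3 and hybridised to Agilent one-colour arrays (1 rat per array, 3 per group), per the labels. Groups, days and doses were taken from the sample titles and protocols. The design text speaks of 28 days of dosing, whereas the titles and the treatment protocol also give day 84. Signals were extracted by the authors with Agilent Feature Extraction 10.7.1.1, per the file headers, and the deposited scanner files hold intensity values: background-corrected processed signals and median spot signals per spot. The value table deposited by the authors is on a linear ratio scale: it was checked to equal the processed signal divided by a constant near the 75th percentile of each array (100% of probes within 0.01 log2 of one constant per array, column medians 0.0852 to 0.0978, 75th percentiles 0.996 to 0.998), and 0 of its columns lacked a sample.

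Each array held 62976 spots, of which 1439 were controls. No probe was saturated (0 on any array), and 18 probes marked as outliers on at least 1 array were left out. Probes were named by their RefSeq accession in a table of current rat genes: 28206 of 61537 probes matched 1 gene each (15645 genes), 34683 carried a RefSeq accession, and 33331 were not matched and were not used here. Limiting the tests to matched genes was decided after the files were seen. The coordinates in the files refer to an older genome build than the gene table, so no positions are given.

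Log2 processed signals were scaled by subtracting the 75th percentile of each array. Probes well above background in all 3 arrays of at least 1 group were kept (33790 probes), with 1 probe per gene, the one with the highest mean over 18 arrays, which left 10914 genes. One linear model with a mean per group was fitted to all arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 12 residual and 14.06 total degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, with a threshold of 0.05. The comparisons were DEN and CCl4 against control and CCl4 against DEN at each day, and each compound's effect at day 84 minus that at day 28. Genes lowered by CCl4 alone were those lower than in controls and than with DEN and not called lower with DEN. Shared calls were set beside the product of both counts over the genes tested and beside 20 simulated sets of unchanged groups. Reading and plots used the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

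The gene lists were p53 targets and DNA damage response, cell cycle and DNA replication, extracellular matrix and fibrosis, NRF2 targets and glutathione system, preneoplastic focus and oncofetal markers, xenobiotic cytochrome P450 enzymes, pericentral and periportal hepatocyte markers, hepatocyte secretory and metabolic genes, cholesterol synthesis, fatty acid and triglyceride synthesis, PPARalpha targets and fatty acid oxidation, bile acid synthesis and transport, interferon-stimulated genes, acute phase proteins, endoplasmic reticulum stress and amino acid response, DNA methylation and chromatin regulators, male-predominant and female-predominant liver genes of rats, markers of stellate cells, macrophages, lymphocytes, neutrophils, sinusoidal endothelium, cholangiocytes, erythroid cells, pancreatic acini and adipose tissue, and the 4 genes the study followed up, which come from knowledge of the study. Lists, comparisons and the rule for named genes were fixed before the data were examined. List members were counted by direction, adjusted over all genes and over the list alone, and lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists and the 4 treated against control comparisons (over all lists within each other comparison). A list may share genes with another, and hepatocytes express many genes of the marker lists.

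Named genes were, in each treated against control comparison, the 8 largest rises and 8 largest falls among called genes with a symbol whose 3 treated arrays all lay on one side of the 3 controls, up to 3 called members of each list with the smallest adjusted p, the first 3 members of a list as values, and the followed-up genes. Some genes that this rule names are not reported here. In other comparisons these were the 5 largest rises and falls, without the condition on arrays for differences between days, and the 10 largest falls among genes lowered by CCl4 alone.

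Alternatives were normexp background correction with an offset of 50 (on the median spot signal, since the files hold no mean signal), no filter on dim probes (15642 genes), only probes well above background on all arrays (9239 genes), scaling to the median of the tested probes, quantile normalization, an estimated camera correlation, a replicate block, all probes, leaving out each array, only the groups compared, arrays of one slide only, slide as a fixed or a random block (consensus correlation 0.192), at least 2-fold change, the authors' value table, eBayes with a trend, and, added after the data were seen, scaling to the spike-in probes. Leaving out the arrays of the third slide, also added then, is the one-slide fit at day 84. The fit was tested on simulated data of 10914 genes, 67, 67 and 66 changed 1.5-, 2- and 4-fold. Far more were called here, so rates may not carry over. Of genes changed 2-fold, 83.6% with DEN and 85.1% with CCl4 at day 28 and 88.1% and 80.6% at day 84 were called. Of genes changed 1.5-fold, 38.8% to 68.7% were. False calls were 4 to 17 (17 with DEN at day 28, beside 46, 56 and 64 true ones), with 0 wrong signs. Of 5503 genes with several probes, 4, 58, 38 and 56 had probes with opposite calls (same order).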

Results

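Liver RNA from male F344 rats was measured on Agilent one-colour arrays, 1 rat per array. The 18 arrays formed 6 groups of 3 rats: controls, rats given N-nitrosodiethylamine (DEN) and rats given carbon tetrachloride (CCl4), each at day 28 and day 84 of dosing. DEN, a genotoxic nitrosamine that alkylates DNA, was given at 4 mg/kg in saline. CCl4, which damages hepatocytes without being genotoxic, was given at 100 mg/kg in corn oil. Both were given daily by gavage at 5 mL/kg. Sample titles call the controls vehicle, whereas the protocol describes untreated rats on a basal diet, so it is open whether gavage and vehicle were matched. The series title asks which genes are lowered in liver by hepatocarcinogens that are not genotoxic. DNA methylation, which it also names, was not analysed here.

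Between 47.2% and 57.0% of the 61537 probes of an array were well above background. The 75th percentile of the processed signal lay between 170 and 325. Values of the 10914 genes tested are log2 fold changes ± the standard error (SE) of the limma fit with n = 3 rats per group, unless a fold is named. A gene was called when its adjusted p was under 0.05, and "rose" and "fell" are used of called genes. Counts of measured members marked alone are adjusted over the list alone. A second camera p, marked estimated, uses an estimated correlation and is adjusted too. A note such as "not called without DEN 1/3" names replicates whose omission ends a call. Gene p-values pool the spread of all groups, and n = 3 limits precision. SEs are too small for more variable groups and too large for others. Camera p-values use the spread across genes. Where no array of a group was well above background, a bound (at least N-fold) compares the means of the brighter and the dim group. In the latter each array counts with the higher of the lowest signal among its probes well above background and the probe's own signal.

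Pearson correlations across genes between arrays of one group ran from 0.976 to 0.996 (genes are not independent replicates). The first principal component held 58.9% of the variance, with controls between −56.8 and −48.9 and CCl4 arrays between 25.4 and 75.7. Replicate 2 of the CCl4 group at day 28 scored 75.7, apart from 38.1 and 25.4 for its group. DEN arrays at day 84 had the lowest scores on the second component, which held 12.8% of the variance. The arrays sat on 3 slides. At day 28, replicate 3 of CCl4 lay on another slide than its controls. At day 84, replicates 2 and 3 of CCl4 lay on the third slide, scanned on another day. With slide as a block, CCl4 effects therefore rest on replicates 1 and 2 at day 28 and on replicate 1 alone at day 84.

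The 75th percentile, to which the arrays were scaled, was itself higher over the spike-in probes in treated than in control arrays. The rise was 0.38 with DEN and 0.78 with CCl4 at day 28, and 0.56 and 0.51 at day 84. Scaling to the spike-in probes (spike-in scaling) adds these constants to every gene, so list shifts against all genes stay the same while calls can change. The median change of all genes moved from −0.04 to 0.33 with DEN and from −0.06 to 0.71 with CCl4 at day 28. At day 84 it moved from −0.08 to 0.49 and from −0.10 to 0.42. Directions are therefore relative to the 75th percentile, and a called list whose median changes sign with spike-in scaling or quantile normalization carries that median beside it.

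**Figure D1:**
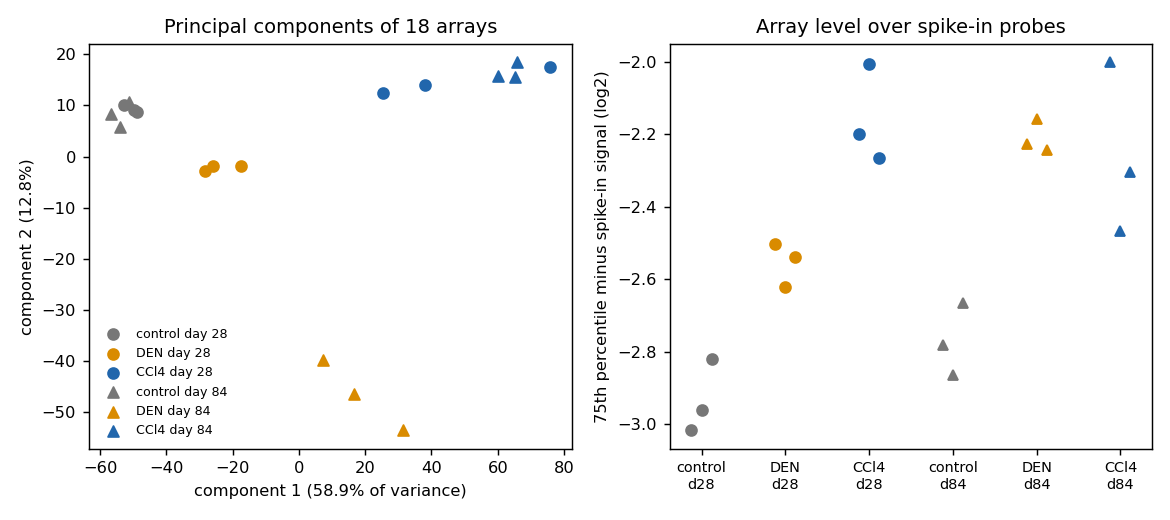
Scores of the 18 arrays on the first and second principal components, and the log2 75th percentile of each array minus its log2 spike-in signal, with points for single arrays (colour for treatment, circles for day 28, triangles for day 84). Controls lie between −56.8 and −48.9 on the first component, replicate 2 of CCl4 at day 28 lies at 75.7, and the group means of the percentile over the spike-in run from −2.93 in controls to −2.16 with CCl4 at day 28.

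DEN against control at day 28 shows the early response to the genotoxic compound. Targets of p53, the transcription factor activated by DNA damage, rose. Ccng1, which encodes cyclin G1, was 6.04-fold higher with DEN (2.60 ± 0.11, adjusted p = 7.30e-09), and Mdm2, the ubiquitin ligase that limits p53, was 3.73-fold higher (1.90 ± 0.12, adjusted p = 1.84e-07). Bax, a promoter of apoptosis, and Mgmt, which removes alkyl groups from guanine, were 2.42-fold (1.27 ± 0.075) and 4.68-fold (2.23 ± 0.13) higher. Of the p53 list, 15 of 23 members rose and 3 fell (17 and 5 alone). Their median was 1.19 (camera adjusted p = 2.69e-12 and 0.0481 estimated). Cdkn1a, the p53 target that encodes p21, was not called (−0.27 ± 0.12, adjusted p = 0.148). In limma, 1639 genes changed with DEN, 854 higher and 785 lower, and 368 of them changed at least 2-fold.

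The largest changes were taken from called genes whose 3 treated arrays all lay on one side of the 3 controls, which chance gives in 10% of genes. Rises with DEN were led by Pln (6.90 ± 0.37, 1 of 3 control arrays well above background), Abcb1b (5.16 ± 0.18), Vxn (5.52 ± 0.32), Hapln3 (5.11 ± 0.28, 2 of 3 control arrays well above background) and Lama5 (4.65 ± 0.34). In genes dim in controls they were led by Mybl2 (at least 44.1-fold higher), Plcd4 (at least 20.7-fold higher) and Svop (at least 8.23-fold higher). Abcb1b encodes a P-glycoprotein that exports drugs, and Mybl2 a transcription factor of dividing cells. The largest falls included Inmt (−5.17 ± 0.82), Cd14 (−3.05 ± 0.20), Noct (−2.89 ± 0.77, not called without control 1/3 or DEN 1/3, at −2.86 to −2.72) and Ropn1l (−2.27 ± 0.55, 1 of 3 DEN arrays well above background, not called without control 3 or DEN 2, at −1.76). Among them were also Nr0b2 (−2.25 ± 0.42), Ppp1r3c (−2.20 ± 0.34), Tenm2 (at least 4.83-fold lower) and Fibin (at least 1.91-fold lower). Cd14 encodes a receptor for bacterial lipopolysaccharide and Nr0b2 a nuclear receptor that represses bile acid synthesis.

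Genes of detoxification rose in part. Of NRF2 targets and the glutathione system, 8 of 28 members rose and 1 fell (9 and 1 alone). Their median was 0.30 (camera adjusted p = 0.000153 and 0.643 estimated). They included Aldh1a1 (3.58 ± 0.21), Ephx1 (1.42 ± 0.12) and Gstp1 (0.84 ± 0.11). Of cell cycle genes, 11 of 32 members rose and 0 fell (23 and 0 alone). Their median was 0.77 (camera adjusted p = 8.53e-11 and 0.643 estimated). Tyms, which makes thymidylate, was at 1.22 ± 0.14 and Ccnd1, cyclin D1, at 1.12 ± 0.16. Markers of lymphocytes rose beside them: 7 of 19 members rose and 0 fell (7 and 0 alone). Their median was 0.55 (camera adjusted p = 2.49e-05 and 0.466 estimated, median 0.39 with dim members at their bounds). The T cell genes Cd3d (1.30 ± 0.18) and Cd3g (1.11 ± 0.17) were among them. Of genes of extracellular matrix, 5 of 23 members rose and 0 fell (5 and 1 alone), with Timp1 (1.08 ± 0.26, not called without DEN 1, at 0.92) and Tgfb1 (0.52 ± 0.12, not called without DEN 1, at 0.47). Their median was 0.46 (camera adjusted p = 0.000348 and 0.660 estimated), and the call was lost with spike-in scaling.

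Cholesterol synthesis fell with DEN at day 28. Of its list, 0 of 23 members rose and 11 fell (0 and 20 alone), including Hmgcs1 (−0.86 ± 0.18) and Idi1 (−0.95 ± 0.21). Their median was −0.54 (camera adjusted p = 9.81e-07 and 0.660 estimated). Of hepatocyte secretory and metabolic genes, 0 of 27 members rose and 6 fell (0 and 13 alone), among them Hnf4a (−0.67 ± 0.13) and Tat (−1.63 ± 0.36, not called without DEN 1, at −1.40). Their median was −0.33 (camera adjusted p = 3.71e-05 and 0.660 estimated, median 0.048 with spike-in scaling). Of acute phase proteins, 2 of 22 members rose and 6 fell (2 and 11 alone). Their median was −0.31 (camera adjusted p = 0.00498 and 0.660 estimated, median 0.068 with spike-in scaling). Both of these last calls were lost with quantile normalization. Of fatty acid and triglyceride synthesis, 0 of 17 members rose and 1 fell (0 and 1 alone). Their median was −0.49 (camera adjusted p = 0.00244 and 0.660 estimated). The member that fell was Mlxipl (−0.45 ± 0.12, not called without control 1/3 or DEN 1/2, at −0.46 to −0.41), a transcription factor that responds to carbohydrate.

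Stellate cell and focus markers were not called with DEN at day 28: hepatic stellate cell and myofibroblast markers (0 rose and 0 fell of 12, adjusted p = 0.117) and preneoplastic focus and oncofetal markers (3 rose and 1 fell of 20, 4 and 2 over the list alone, adjusted p = 0.0890). Nor were xenobiotic cytochrome P450 enzymes (2 rose and 2 fell of 24, 2 and 3 over the list alone, adjusted p = 0.216), periportal hepatocyte markers (2 rose and 2 fell of 18, adjusted p = 0.230), PPARalpha targets and fatty acid oxidation (0 rose and 3 fell of 22, adjusted p = 0.254) and cholangiocyte and ductular cell markers (0 rose and 0 fell of 11, adjusted p = 0.537). DEN and control arrays of this day shared 1 slide, and with slide as a block 1901 genes were called with identical list shifts. The share of higher genes was 52.1%, against 97.9% of 3906 called genes with spike-in scaling and 65.0% with quantile normalization, and leaving out single arrays gave 700 to 1319 genes.

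CCl4 against control at day 28 shows the response to CCl4 and any unmatched corn oil. Genes of cell division rose: Mki67, a marker of dividing cells, was 9.96-fold higher (3.32 ± 0.20, adjusted p = 4.40e-08) and Aurka, a kinase of mitosis, 6.93-fold higher (2.79 ± 0.14, adjusted p = 8.06e-09). Genes of fibrosis rose with them, among them Timp1, an inhibitor of matrix proteases, 12.5-fold higher (3.64 ± 0.26), and Col1a1, a chain of type I collagen, 6.26-fold higher (2.65 ± 0.37). Genes of hepatocyte function fell, with Alb, which encodes albumin, at −1.08 ± 0.13 and Hnf4a, a transcription factor of hepatocyte identity, at −1.47 ± 0.13. In limma, 6514 genes changed, 2846 higher and 3668 lower, and 2064 changed at least 2-fold.

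Leading rises were Cyp2c24 (7.06 ± 0.27, 1 of 3 control arrays well above background), Trem2 (7.06 ± 0.78, 1 of 3 control arrays well above background), Cox6a2 (5.78 ± 0.27) and Acsm5 (5.74 ± 0.27). In genes dim in controls they were Acot1 (at least 399.8-fold higher), Mmp12 (at least 64.2-fold higher), Sdcbp2 (at least 36.3-fold higher) and Colq (at least 17.7-fold higher). Mmp12 is the elastase of macrophages and Trem2 a receptor of the same cells. Leading falls were Stac3 (−8.89 ± 0.78, 2 of 3 CCl4 arrays well above background), Inmt (−8.72 ± 0.82, 1 of 3 CCl4 arrays well above background), Mup4 (−8.06 ± 1.32, 2 of 3 CCl4 arrays well above background) and Aox3 (−7.19 ± 0.81, 1 of 3 CCl4 arrays well above background). Then came Ltc4s (−6.24 ± 0.39, 1 of 3 CCl4 arrays well above background), Car3 (−5.52 ± 0.75), Cyp2c11 (−5.40 ± 0.92) and Zfp354a (−4.72 ± 0.51). Mup4 is a major urinary protein, Cyp2c11 a cytochrome P450 of male rat liver and Aox3 an aldehyde oxidase.

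Of the cell cycle list, 32 of 32 members rose and 0 fell (32 and 0 alone). Their median was 3.23 (camera adjusted p = 2.06e-19 and 0.466 estimated). Of extracellular matrix genes, 19 of 23 members rose and 1 fell (19 and 1 alone). Their median was 1.71 (camera adjusted p = 3.58e-07 and 0.643 estimated, median 1.54 with dim members at their bounds). Stellate cell and myofibroblast markers rose beside the matrix genes: 9 of 12 members rose and 0 fell (11 and 0 alone). Their median was 1.29 (camera adjusted p = 0.000688 and 0.660 estimated, median 1.13 with dim members at their bounds). Of markers of preneoplastic foci, 14 of 20 members rose and 2 fell (15 and 3 alone), with Gpx2 (5.38 ± 0.32), Abcc3 (2.73 ± 0.24) and Gstp1 (1.75 ± 0.11). Their median was 1.77 (camera adjusted p = 0.00109 and 0.660 estimated). Of NRF2 targets, 13 of 28 members rose and 5 fell (14 and 5 alone). Their median was 0.25 (camera adjusted p = 0.0207 and 0.676 estimated). Markers of cholangiocytes and ductular cells also rose: 6 of 11 members rose and 0 fell (6 and 0 alone). Their median was 0.81 (camera adjusted p = 0.0174 and 0.660 estimated). They included Spp1 (5.43 ± 0.45, 1 of 3 control arrays well above background), Sctr (at least 3.19-fold higher) and Cldn7 (1.43 ± 0.33). The calls of the stellate, preneoplastic, NRF2 and cholangiocyte lists were lost with spike-in scaling at unchanged shifts, that of NRF2 also with slide as a block and that of cholangiocytes also with normexp, quantile normalization and the all-array filter.

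**Figure D2:**
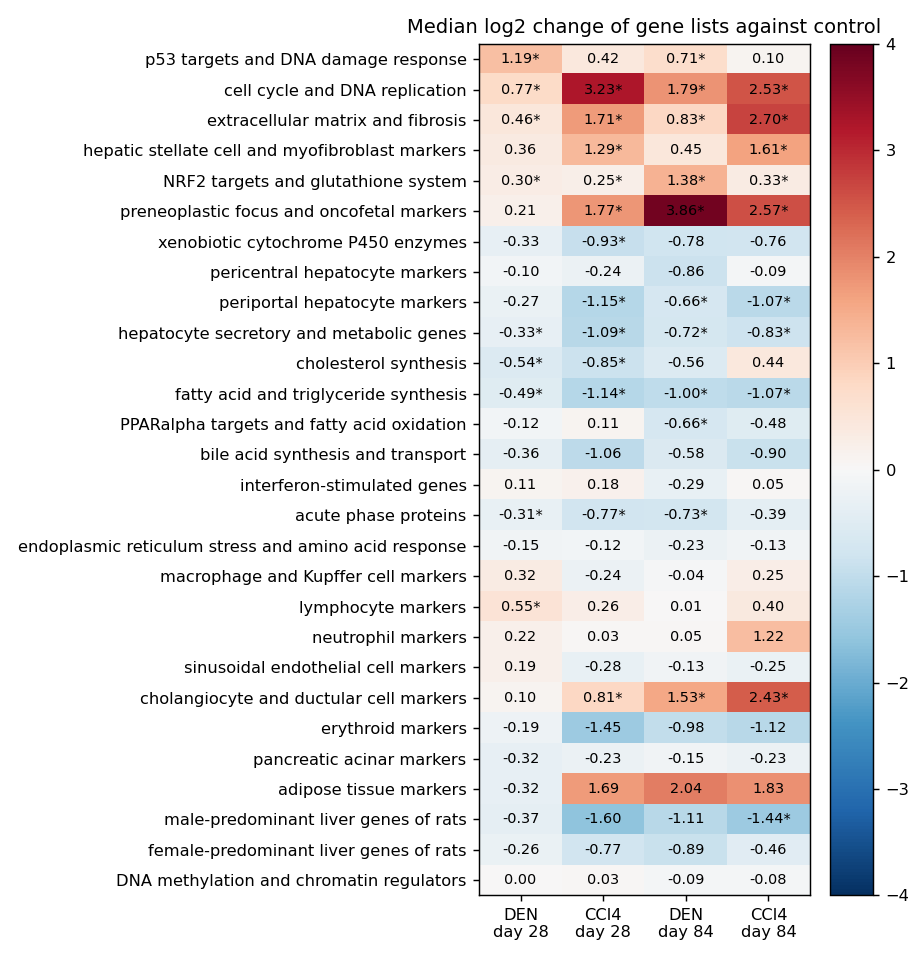
Median log2 fold change of 28 gene lists (vertical) in the 4 treated against control comparisons (horizontal), as a colour scale with the value in each cell and a star where the camera adjusted p was under 0.05. The cell cycle list had a median of 3.23 with CCl4 at day 28 and the p53 list one of 1.19 with DEN at day 28, whereas hepatocyte secretory genes had −0.33 with DEN at day 28, which was 0.048 with spike-in scaling, one of several medians under 0 that changed sign.

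Of hepatocyte secretory and metabolic genes, 0 of 27 members rose and 27 fell (0 and 27 alone), with Otc (−1.84 ± 0.18), an enzyme of the urea cycle. Their median was −1.09 (camera adjusted p = 3.52e-09 and 0.660 estimated). Of periportal markers, 0 of 18 members rose and 16 fell (0 and 16 alone), with Ass1 (−1.85 ± 0.21), an enzyme of the same cycle. Their median was −1.15 (camera adjusted p = 1.82e-05 and 0.660 estimated). Of xenobiotic cytochrome P450 enzymes, 2 of 24 members rose and 18 fell (2 and 18 alone), with Cyp1a2 (−1.49 ± 0.36) and Cyp2c23 (−1.099 ± 0.15). Their median was −0.93 (camera adjusted p = 0.00792 and 0.758 estimated). Of cholesterol synthesis, 0 of 23 members rose and 20 fell (0 and 20 alone), with Hmgcs1 (−1.02 ± 0.18) and Insig1 (−2.67 ± 0.30). Their median was −0.85 (camera adjusted p = 0.000105 and 0.660 estimated). Of fatty acid and triglyceride synthesis, 0 of 17 members rose and 13 fell (0 and 13 alone), with Fasn (−2.68 ± 0.41) and Scd (−2.63 ± 0.32). Their median was −1.14 (camera adjusted p = 0.000535 and 0.660 estimated). Of acute phase proteins, 2 of 22 members rose and 16 fell (3 and 16 alone), with Lbp (1.85 ± 0.19) and C3 (−0.88 ± 0.097) on opposite sides. Their median was −0.77 (camera adjusted p = 0.00566 and 0.660 estimated, median 0.011 with spike-in scaling), and the call was lost with quantile normalization.

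The p53 list was not called with CCl4 at day 28: 11 of 23 members rose and 6 fell (11 and 6 alone). Their median was 0.42 (camera adjusted p = 0.152). It was called higher with normexp (adjusted p = 0.0438) and with no filter on dim probes (adjusted p = 0.0290). Its changed members included Fas (2.21 ± 0.18), Sesn2 (−2.07 ± 0.12) and Xpc (−0.99 ± 0.092). Fas encodes a death receptor and Xpc a protein of nucleotide excision repair. Macrophage genes moved in both directions, Gpnmb (3.42 ± 0.18) and Ccl2 (3.50 ± 0.55, 1 of 3 control arrays well above background) against Clec4f (−1.78 ± 0.32), a marker of resident Kupffer cells. The amino acid and stress genes Phgdh (5.05 ± 0.25) and Atf3 (4.49 ± 0.31) rose, while their list went both ways and was not called. Also not called were PPARalpha targets and fatty acid oxidation (6 rose and 7 fell of 22, adjusted p = 0.549) and lymphocyte markers (7 rose and 5 fell of 19, adjusted p = 0.452).

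With slide as a block 6667 genes were called with CCl4 at day 28, and 6551 on one slide alone. Blocked shifts of lists against all genes (unblocked in parentheses) were 3.48 (3.30) for cell cycle, 1.91 (1.77) for matrix, 1.65 (1.36) for stellate, 0.44 (0.31) for NRF2, 2.08 (1.83) for preneoplastic and 1.32 (0.88) for cholangiocyte genes. They were −1.18 (−1.03) for hepatocyte, −1.20 (−1.08) for periportal, −1.12 (−0.87) for P450, −0.82 (−0.79) for cholesterol and −1.17 (−1.08) for fatty acid genes. The share of higher genes was 43.7%, and 93.8% with spike-in scaling.

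CCl4 against DEN at day 28 asks which genes set the compounds, each with its vehicle, apart. Cell cycle genes were higher with CCl4: 30 of 32 members were higher and 0 lower. Their median was 2.43 (camera adjusted p = 4.04e-20 and 0.243 estimated). Targets of p53 were lower: 1 of 23 members were higher and 17 lower. Their median was −0.52 (camera adjusted p = 1.28e-06 and 0.155 estimated). Genes higher with CCl4 were led by Cox6a2 (6.65 ± 0.27), Acot1 (at least 439-fold higher), Sdcbp2 (at least 39.8-fold higher), Trem2 (6.37 ± 0.78, 1 of 3 DEN arrays well above background) and Gucy2c (at least 13.4-fold higher). Genes lower were led by Stac3 (−6.98 ± 0.78, 2 of 3 CCl4 arrays well above background), Aox3 (−6.03 ± 0.81, 1 of 3 CCl4 arrays well above background), Mup4 (−5.65 ± 1.32, 2 of 3 CCl4 arrays well above background, −3.36 without CCl4 2), Ltc4s (−5.23 ± 0.39, 1 of 3 CCl4 arrays well above background) and Car3 (−5.15 ± 0.75). In limma, 4918 genes differed, 2225 higher with CCl4 and 2693 lower.

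Further lists higher with CCl4 than with DEN were matrix (median 1.14, camera adjusted p = 3.57e-06 and 0.456 estimated) and stellate genes (median 1.03, camera adjusted p = 0.00128 and 0.456 estimated). So were preneoplastic (median 1.15, camera adjusted p = 0.000716 and 0.456 estimated, median 1.27 with dim members at their bounds) and cholangiocyte markers (median 0.93, camera adjusted p = 0.0111 and 0.486 estimated). Lower lists were periportal (median −0.99, camera adjusted p = 8.61e-07 and 0.456 estimated) and hepatocyte secretory genes (median −0.76, camera adjusted p = 5.49e-08 and 0.456 estimated). Fatty acid synthesis (median −0.75, camera adjusted p = 0.00544 and 0.623 estimated) and P450 enzymes (median −0.54, camera adjusted p = 0.0111 and 0.672 estimated) were lower too. The same held for acute phase proteins (median −0.48, camera adjusted p = 0.0149 and 0.623 estimated) and sinusoidal endothelial markers (median −0.45, camera adjusted p = 0.00345 and 0.456 estimated). With slide as a block 5293 genes differed, 5131 on one slide alone. The share higher with CCl4 was 45.2%, and 88.1% with spike-in scaling, which moved the median of all genes from −0.03 to 0.37.

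Genes lowered by CCl4 alone at day 28 bear on the question of the series title. They were lower than in controls, lower than with DEN, and not called lower with DEN: 2032 genes, 535 of them at least 2-fold lower than in controls. The 10 with the largest falls were Stac3, Mup4, Aox3, Ltc4s, Car3, Cyp2c11 and Zfp354a, given above, and Mup4l3 (−4.46 ± 1.35, −2.17 without CCl4 2), Nox4 (−4.33 ± 0.61, 1 of 3 CCl4 arrays well above background) and Dhrs7l1 (−4.06 ± 1.05, −2.36 without CCl4 2). At day 84, 1755 of the 2032 (86.4%) were lower with CCl4, against 738 expected for sets of these sizes, and 14 were higher. By then 1340 (65.9%) were also lower with DEN, 643 were lower with CCl4 than control and DEN, and 339 of those were not called lower with DEN. Of the 10 genes, Aox3 (−4.74 ± 0.81), Stac3 (−4.07 ± 0.78), Mup4 (−3.99 ± 1.32, not called without control 1/2 or DEN 2, at −3.98 to −3.52), Nox4 (−3.56 ± 0.61, 1 of 3 DEN arrays well above background), Ltc4s (−3.02 ± 0.39) and Car3 (−1.99 ± 0.75, not called without control 1/2/3 or DEN 1/2, at −2.17 to −1.52) fell with DEN at day 84. Not called were Cyp2c11 (−1.93 ± 0.92), Mup4l3 (−1.32 ± 1.35), Dhrs7l1 (−1.12 ± 1.05) and Zfp354a (0.0088 ± 0.51). The count was 393 with spike-in scaling and 1339 without replicate 2 of CCl4 at day 28, where the difference of Mup4l3 from DEN lost its call, at −1.48, as it did without DEN 1, 2 or 3 (−3.80 to −3.75).

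The study followed up 4 genes, Ldlrad4, Proc, Cdh17 and Nfia, known from it, not the labels. They may have been chosen on these samples, so no fall or list test is independent evidence. Ldlrad4 limits TGF-beta signalling, Proc encodes the anticoagulant protein C, Cdh17 a cadherin and Nfia a transcription factor. With CCl4 at day 28 all 4 fell: Ldlrad4 (−1.09 ± 0.095), Proc (−1.43 ± 0.15), Cdh17 (−1.08 ± 0.34, not called without CCl4 2, at −0.94) and Nfia (−1.63 ± 0.11). Their median was −1.26 (camera adjusted p = 0.00773 and 0.466 estimated), and 4 were lower over the list alone. With DEN at day 28 the values were Ldlrad4 (−0.34 ± 0.095, 0.035 with spike-in scaling, not called without control 2/3 or DEN 1/2, at −0.37 to −0.27), Proc (−0.23 ± 0.15, not called), Cdh17 (−0.34 ± 0.34, not called) and Nfia (−0.18 ± 0.11, not called). Their median was −0.28 (camera adjusted p = 0.167, median 0.098 with spike-in scaling), and 1 was lower over the list alone. The call of Ldlrad4 was lost with no filter on dim probes and with only the groups compared. The differences between CCl4 and DEN were Ldlrad4 (−0.75 ± 0.095), Proc (−1.20 ± 0.15), Cdh17 (−0.74 ± 0.34, not called) and Nfia (−1.46 ± 0.11). Their median was −0.97 (camera adjusted p = 0.00386 and 0.243 estimated).

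At day 84 all 4 followed-up genes were lower with DEN as well: Ldlrad4 (−0.41 ± 0.095, 0.15 with spike-in scaling), Proc (−0.76 ± 0.15), Cdh17 (−1.68 ± 0.34) and Nfia (−0.35 ± 0.11, 0.21 with spike-in scaling, not called without DEN 1, at −0.31). Their median was −0.59 (camera adjusted p = 0.0665), with 4 lower over the list alone. With CCl4 they were at Ldlrad4 (−0.70 ± 0.095), Proc (−1.19 ± 0.15), Cdh17 (−3.13 ± 0.34) and Nfia (−1.01 ± 0.11). Their median was −1.097 (camera adjusted p = 0.0123 and 0.466 estimated), with 4 lower over the list alone. Between the compounds at day 84 the differences were Ldlrad4 (−0.29 ± 0.095, not called without DEN 1/2/3 or CCl4 1/3, at −0.29 to −0.26), Proc (−0.42 ± 0.15, not called without DEN 1/3 or CCl4 1/3, at −0.43 to −0.32), Cdh17 (−1.45 ± 0.34) and Nfia (−0.65 ± 0.11). Their median was −0.54 (camera adjusted p = 0.0163 and 0.385 estimated). The differences of Ldlrad4 and Proc lost their calls with slide as a block, on one slide alone and with no filter on dim probes.

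**Figure D3:**
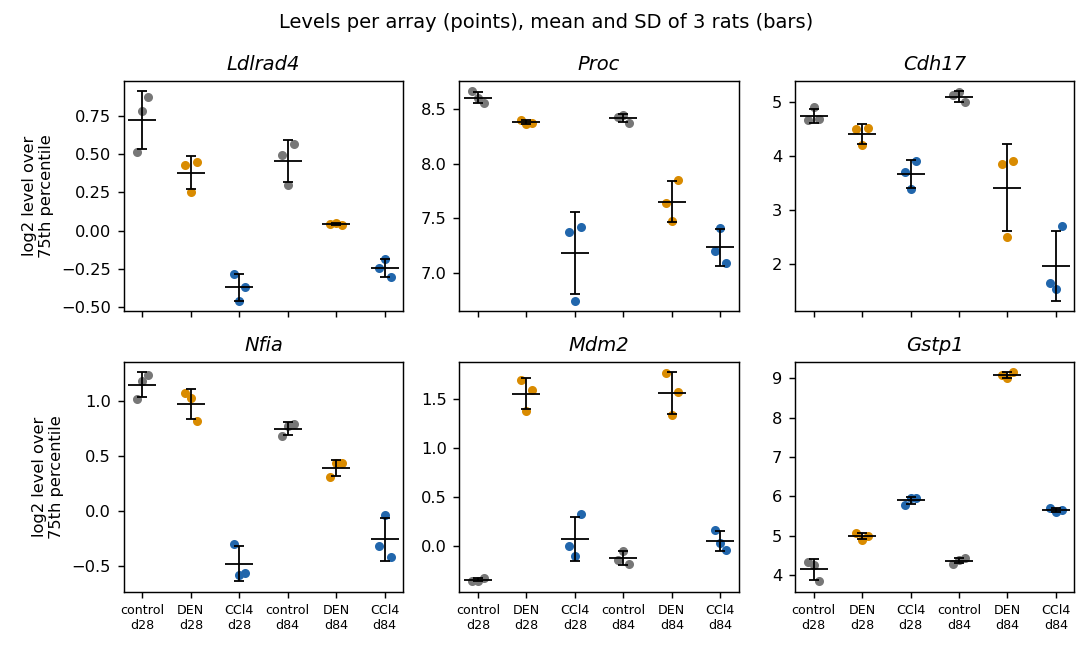
Log2 signal relative to the 75th percentile of the array for Ldlrad4, Proc, Cdh17, Nfia, Mdm2 and Gstp1 in each of the 18 arrays (points), with the mean and SD of each group of 3 (bars). The 4 followed-up genes fell by 1.08 to 1.63 with CCl4 at day 28, while the changes of Ldlrad4 and Nfia with DEN at day 84 (−0.41 and −0.35) were 0.15 and 0.21 with spike-in scaling, and that of Ldlrad4 with DEN at day 28 (−0.34) was 0.035.

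DEN against control at day 84 shows the late response to the genotoxic compound. Gstp1, the placental glutathione transferase used to stain preneoplastic foci, was 26.1-fold higher (4.71 ± 0.11, adjusted p = 1.91e-12). Nqo1, a quinone reductase of the antioxidant response, was 30.1-fold higher (4.91 ± 0.24, adjusted p = 4.41e-09). Akr1b8 and Aldh3a1, which reduce and oxidise aldehydes, were 157-fold (7.29 ± 0.32) and 139-fold (7.12 ± 0.27) higher. In limma, 5750 genes changed, 2354 higher and 3396 lower, and 1493 changed at least 2-fold.

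The leading rises, in genes dim in controls, were Bex1 (at least 371-fold higher), Pcp4 (at least 191-fold higher), Ugt2b7 (at least 167-fold higher) and Slc7a11 (at least 153-fold higher). Next were Cyp2c24 (at least 108-fold higher), Dnaaf1 (at least 73.3-fold higher), Defb1 (at least 52.0-fold higher) and Epdr1 (at least 43.8-fold higher). Slc7a11 is the cystine transporter that feeds glutathione synthesis. The largest falls included Inmt (−6.52 ± 0.82), Aox3 (−4.74 ± 0.81), Stac3 (−4.07 ± 0.78) and Mup4 (−3.99 ± 1.32, not called without control 1/2 or DEN 2, at −3.98 to −3.52). Among them were also Nox4 (−3.56 ± 0.61, 1 of 3 DEN arrays well above background), Lrtm2 (−3.42 ± 0.50), Mmd2 (at least 10.4-fold lower) and Tenm2 (at least 7.62-fold lower).

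Of NRF2 targets, 23 of 28 members rose and 0 fell (23 and 0 alone). Their median was 1.38 (camera adjusted p = 5.39e-17 and 0.118 estimated). Of preneoplastic markers, 17 of 20 members rose and 0 fell (18 and 0 alone), with Ggt1 (5.76 ± 0.58, 1 of 3 control arrays well above background) and Abcc3 (4.75 ± 0.24). Their median was 3.86 (camera adjusted p = 1.49e-11 and 0.253 estimated). Of the p53 list, 14 of 23 members rose and 4 fell (15 and 4 alone), with Ccng1 (2.15 ± 0.11), Mdm2 (1.69 ± 0.12) and Zmat3 (1.34 ± 0.085). Their median was 0.71 (camera adjusted p = 0.000299 and 0.466 estimated). Of cell cycle genes, 32 of 32 members rose and 0 fell (32 and 0 alone), with Mki67 (2.06 ± 0.20) and Rrm2 (3.16 ± 0.29). Their median was 1.79 (camera adjusted p = 3.21e-16 and 0.466 estimated, median 1.59 with dim members at their bounds). Of matrix genes, 14 of 23 members rose and 2 fell (16 and 2 alone). Their median was 0.83 (camera adjusted p = 0.000383 and 0.660 estimated). Col4a1 (1.32 ± 0.23) rose and Fn1 (−0.92 ± 0.11), fibronectin, fell. Col1a1 was not called, at 0.54 ± 0.37. Markers of cholangiocytes and ductular cells rose beside them: 8 of 11 members rose and 2 fell (9 and 2 alone), with Krt19 (2.64 ± 0.42) and Epcam (1.53 ± 0.21). Their median was 1.53 (camera adjusted p = 0.00773 and 0.660 estimated, median 1.22 with dim members at their bounds), and the call was lost with spike-in scaling.

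Hepatocyte genes fell with DEN at day 84: 0 of 27 members rose and 24 fell (0 and 24 alone), with F7 (−0.93 ± 0.13) and Alb (−0.72 ± 0.13). Their median was −0.72 (camera adjusted p = 4.93e-06 and 0.660 estimated). Of periportal markers, 0 of 18 members rose and 12 fell (0 and 13 alone). Their median was −0.66 (camera adjusted p = 0.0117 and 0.751 estimated), and the call was lost with quantile normalization and with normexp. Of PPARalpha targets, 2 of 22 members rose and 16 fell (2 and 16 alone), with Fabp1 (−0.98 ± 0.15), Plin2 (−0.95 ± 0.13) and Pdk4 (−1.56 ± 0.24). Their median was −0.66 (camera adjusted p = 0.00424 and 0.660 estimated). Of fatty acid synthesis, 2 of 17 members rose and 13 fell (2 and 13 alone), with Fads1 (−1.54 ± 0.20) and Elovl5 (−1.37 ± 0.21). Their median was −1.005 (camera adjusted p = 0.00420 and 0.668 estimated). Of acute phase proteins, 1 of 22 members rose and 15 fell (2 and 15 alone), with A2m (2.15 ± 0.50), a protease inhibitor, on the other side. Their median was −0.73 (camera adjusted p = 0.00328 and 0.660 estimated), and the call was lost with quantile normalization.

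Not called with DEN at day 84 were cholesterol synthesis (2 rose and 13 fell of 23, adjusted p = 0.0626) and xenobiotic cytochrome P450 enzymes (4 rose and 15 fell of 24, 4 and 17 over the list alone, adjusted p = 0.116). Cholesterol synthesis was called lower with quantile normalization, the replicate block and only the groups compared (adjusted p = 0.0457, 0.0367 and 0.0222) and without replicate 1 of DEN (adjusted p = 0.0125). Hepatic stellate cell and myofibroblast markers (4 rose and 1 fell of 12, adjusted p = 0.163) and lymphocyte markers (1 rose and 2 fell of 19, 0 and 1 over the list alone, adjusted p = 0.543) were not called either. Single genes of other lists changed: Cyp8b1 (−2.24 ± 0.30), which directs bile acid synthesis to cholic acid, Oat (−3.22 ± 0.37), a pericentral enzyme, and Phgdh (4.56 ± 0.25) and Asns (2.10 ± 0.15), of serine and asparagine synthesis. DEN and control arrays shared 1 slide, and with slide as a block 5974 genes were called with identical list shifts. The share of higher genes was 40.9%, and 93.5% with spike-in scaling.

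CCl4 against control at day 84 shows the late response to CCl4 and any unmatched corn oil. Col1a1 was 8.57-fold higher (3.10 ± 0.37, adjusted p = 8.14e-06), Timp1 12.6-fold higher (3.66 ± 0.26) and Mki67 8.41-fold higher (3.07 ± 0.20). Cyp2c11, the P450 of male rat liver, was 308-fold lower (−8.27 ± 0.92, adjusted p = 5.04e-06), with all 3 CCl4 rats below all 3 controls. In limma, 7013 genes changed, 3051 higher and 3962 lower, and 2402 changed at least 2-fold.

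The largest rises included Acot1 (at least 207-fold higher), Trem2 (at least 189.6-fold higher), Bex1 (at least 104-fold higher) and Cyp2c24 (at least 87.2-fold higher). Among them were also Mmp12 (at least 73.2-fold higher), Cdhr5 (at least 34.7-fold higher), Epdr1 (at least 32.1-fold higher) and Sult2a2 (7.25 ± 0.77, 2 of 3 control arrays well above background). The largest falls, beside Cyp2c11, included Mup4 (−12.03 ± 1.32, 2 of 3 CCl4 arrays well above background), Stac3 (−10.43 ± 0.78), Inmt (at least 631-fold lower) and Dhrs7l1 (−8.37 ± 1.05, 1 of 3 CCl4 arrays well above background). Among them were also Mup4l3 (−8.28 ± 1.35), Mup4l1 (−7.60 ± 1.28) and Aox3 (at least 103-fold lower).

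Of matrix genes, 20 of 23 members rose and 1 fell (21 and 1 alone), with Eln (3.20 ± 0.24), elastin, and Tgfb1 (1.40 ± 0.12). Their median was 2.70 (camera adjusted p = 5.12e-09 and 0.604 estimated, median 2.17 with dim members at their bounds). Stellate cell and myofibroblast markers rose beside them: 9 of 12 members rose and 0 fell (9 and 0 alone), with Vim (2.66 ± 0.24) and Des (2.84 ± 0.35). Their median was 1.61 (camera adjusted p = 0.00104 and 0.660 estimated). Of cell cycle genes, 32 of 32 members rose and 0 fell (32 and 0 alone). Their median was 2.53 (camera adjusted p = 6.78e-16 and 0.466 estimated). Of preneoplastic markers, 16 of 20 members rose and 1 fell (16 and 1 alone), with Gpx2 (5.75 ± 0.32) and Gstp1 (1.29 ± 0.11). Their median was 2.57 (camera adjusted p = 2.86e-06 and 0.466 estimated, median 2.80 with dim members at their bounds). Of NRF2 targets, 14 of 28 members rose and 6 fell (14 and 6 alone). Their median was 0.33 (camera adjusted p = 0.0178 and 0.668 estimated). Cholangiocyte and ductular markers rose too: 9 of 11 members rose and 1 fell (9 and 2 alone), with Spp1 (3.98 ± 0.45, 2 of 3 control arrays well above background), Epcam (1.73 ± 0.21) and Cftr (at least 21.9-fold higher). Their median was 2.43 (camera adjusted p = 0.00326 and 0.660 estimated). The calls of the NRF2 and cholangiocyte lists were lost with spike-in scaling.

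Of hepatocyte secretory genes, 0 of 27 members rose and 25 fell (0 and 25 alone), with Hnf4a (−1.03 ± 0.13), Cebpa (−1.23 ± 0.16) and Otc (−1.40 ± 0.18). Their median was −0.83 (camera adjusted p = 1.71e-05 and 0.660 estimated). Of periportal markers, 0 of 18 members rose and 16 fell (0 and 16 alone), with Hal (−2.82 ± 0.26). Their median was −1.07 (camera adjusted p = 0.000412 and 0.660 estimated). Of fatty acid synthesis, 1 of 17 members rose and 12 fell (1 and 13 alone), with Pklr (−2.10 ± 0.27) and Elovl5 (−1.60 ± 0.21). Their median was −1.07 (camera adjusted p = 0.00373 and 0.668 estimated). Cholesterol synthesis was not called at day 84: 10 of 23 members rose and 3 fell (10 and 3 alone), with Sqle (2.39 ± 0.23). Their median was 0.44 (camera adjusted p = 0.121). It was called higher with normexp, quantile normalization, no filter on dim probes and the all-array filter (adjusted p = 0.0239, 0.0457, 0.0288 and 0.0378).

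The p53 list was not called: 7 of 23 members rose and 9 fell (7 and 9 alone). Their median was 0.10 (camera adjusted p = 0.793). Mdm2 was at 0.18 ± 0.12 (not called). Nor were xenobiotic cytochrome P450 enzymes (3 rose and 15 fell of 24, adjusted p = 0.100) and PPARalpha targets and fatty acid oxidation (3 rose and 14 fell of 22, adjusted p = 0.133). Also not called were lymphocyte markers (7 rose and 5 fell of 19, adjusted p = 0.501) and acute phase proteins (4 rose and 13 fell of 22, adjusted p = 0.303, median −0.39 and mean 0.15 with the test pointing down), although Lbp (2.30 ± 0.19) and Lcn2 (at least 18.3-fold higher) rose.

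With slide as a block 5891 genes were called for CCl4 at day 84, and 5722 on one slide alone. Both rest on replicate 1 of CCl4, assumed to vary like the others, and check no other rat. Blocked shifts against all genes (unblocked in parentheses) were 2.46 (2.62) for cell cycle, 2.71 (2.80) for matrix, 1.80 (1.71) for stellate, 2.85 (2.67) for preneoplastic, 0.61 (0.42) for NRF2 and 2.71 (2.53) for cholangiocyte genes. They were −0.75 (−0.73) for hepatocyte, −0.96 (−0.97) for periportal and −0.91 (−0.97) for fatty acid genes. The share of higher genes was 43.5%, and 87.4% with spike-in scaling.

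**Figure D4:**
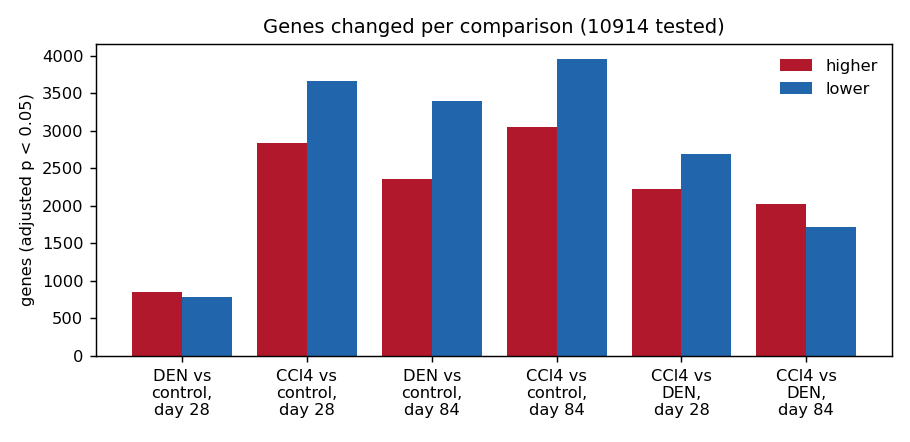
Number of genes (vertical) called higher and lower, as pairs of bars, in the 6 comparisons of 2 groups (horizontal), of 10914 tested. Calls run from 1639 with DEN at day 28 to 7013 with CCl4 at day 84, and the lower genes outnumber the higher ones in both CCl4 against control comparisons, which spike-in scaling turns to 93.8% and 87.4% higher.

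CCl4 against DEN at day 84 sets the late responses, each with its vehicle, side by side. Antioxidant genes of the NRF2 list were lower with CCl4 than with DEN: 0 of 28 members were higher and 25 lower. Their median was −1.24 (camera adjusted p = 1.41e-17 and 0.0558 estimated). Targets of p53 were lower too: 1 of 23 members were higher and 14 lower. Their median was −0.56 (camera adjusted p = 2.02e-06 and 0.0857 estimated). Matrix genes were higher with CCl4: 20 of 23 members were higher and 0 lower. Their median was 1.46 (camera adjusted p = 1.10e-09 and 0.390 estimated). So was cholesterol synthesis: 19 of 23 members were higher and 1 lower. Their median was 0.72 (camera adjusted p = 2.02e-06 and 0.642 estimated). Genes higher with CCl4 were led by Cox6a2 (6.55 ± 0.27), Acot1 (5.60 ± 0.47), Sult2a2 (5.28 ± 0.77), Cthrc1 (at least 16.6-fold higher) and Atp6v0d2 (at least 9.63-fold higher). Those lower were led by Pcp4 (at least 283-fold lower), Mup4 (−8.04 ± 1.32, 2 of 3 CCl4 arrays well above background), Dnaaf1 (at least 109-fold lower), Ugt2b7 (−7.78 ± 0.31) and Trim54 (at least 66.9-fold lower). In limma, 3743 genes differed, 2021 higher with CCl4 and 1722 lower.

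Stellate (median 1.41, camera adjusted p = 0.000979 and 0.642 estimated) and cell cycle genes (median 0.74, camera adjusted p = 2.60e-05 and 0.642 estimated) were also higher with CCl4. So were pericentral markers (median 0.59, camera adjusted p = 0.00263 and 0.642 estimated) and acute phase proteins (median 0.25, camera adjusted p = 0.00559 and 0.642 estimated). Preneoplastic markers, 7 higher and 11 lower, were lower as a list (median −0.99, camera adjusted p = 0.0113 and 0.642 estimated), and so were periportal markers (median −0.45, camera adjusted p = 0.0133 and 0.654 estimated). With slide as a block 2012 genes differed and on one slide alone 1812. The share higher with CCl4 was 54.0%, and 49.7% of 2378 genes with spike-in scaling.

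Further lists were not called in any of the 4 comparisons against control, given here in the order DEN and CCl4 at day 28, then DEN and CCl4 at day 84. Of 18 pericentral hepatocyte markers, 3, 5, 1 and 5 rose and 2, 8, 12 and 5 fell (4, 5, 2 and 5 and 3, 8, 12 and 5 over the list alone), with camera adjusted p = 0.710, 0.744, 0.0582 and 0.845. With DEN at day 84 they were called lower with quantile normalization, median scaling, the all-array filter and the replicate block (adjusted p = 0.0251, 0.0481, 0.0346 and 0.0264) and without replicate 3 of DEN (adjusted p = 0.0115). Of 18 genes of bile acid synthesis and transport, 0, 3, 3 and 2 rose and 2, 13, 11 and 12 fell (1, 3, 3 and 2 and 5, 13, 11 and 12 over the list alone), with camera adjusted p = 0.0896, 0.0652, 0.155 and 0.133. With CCl4 at day 28 they were called lower without replicate 3 of CCl4 (adjusted p = 0.0256), to which slide as a block and one slide alone amount (adjusted p = 0.0331 and 0.0351). They were so too with the replicate block and quantile normalization (adjusted p = 0.0465 and 0.0469). Of 22 interferon-stimulated genes, 4, 7, 4 and 5 rose and 1, 6, 9 and 6 fell (5, 7, 4 and 5 and 1, 6, 9 and 6 over the list alone), with camera adjusted p = 0.163, 0.444, 0.361 and 0.845. Of 21 genes of endoplasmic reticulum stress and amino acid response, 2, 8, 4 and 5 rose and 4, 7, 7 and 8 fell (3, 8, 4 and 5 and 7, 7, 7 and 8 over the list alone), with camera adjusted p = 0.187, 0.602, 0.961 and 0.899. Of 20 macrophage and Kupffer cell markers, 2, 4, 2 and 8 rose and 1, 7, 3 and 7 fell (the same over the list alone), with camera adjusted p = 0.0907, 0.872, 0.845 and 0.351. Of 5 neutrophil markers, 0, 1, 0 and 4 rose and 0, 0, 0 and 1 fell (the same over the list alone), with camera adjusted p = 0.443, 0.793, 0.817 and 0.262. Of 12 sinusoidal endothelial markers, 1, 0, 2 and 2 rose and 0, 4, 5 and 6 fell (0, 0, 3 and 2 and 0, 4, 5 and 6 over the list alone), with camera adjusted p = 0.0896, 0.134, 0.793 and 0.229. Of 7 erythroid markers, 0, 1, 0 and 3 rose and 0, 4, 5 and 4 fell (the same over the list alone), with camera adjusted p = 0.879, 0.210, 0.222 and 0.989, and their shift of −1.02 with CCl4 at day 84 was 0.071 for replicate 1 alone, the blocked value. Of 6 pancreatic acinar markers, 0, 1, 1 and 2 rose and 0, 1, 0 and 1 fell (the same over the list alone), with camera adjusted p = 0.558, 0.916, 0.707 and 0.827. Of 3 adipose markers, 1, 2, 2 and 2 rose and 0, 1, 1 and 0 fell (1, 2, 2 and 2 and 2, 1, 1 and 0 over the list alone), with camera adjusted p = 0.922, 0.393, 0.167 and 0.125.

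Median, mean and test of a list differed in sign in places. With DEN at day 28 this held for pericentral (median −0.10, mean 0.094, test up) and adipose markers (−0.32, 0.037, down). With CCl4 at day 28 it held for macrophage (−0.24, 0.28, down), stress (−0.12, 0.43, up) and pancreatic lists (−0.23, −0.053, up). With DEN at day 84 it held for stress (−0.23, 0.31, up), macrophage (−0.04, 0.11, up) and pancreatic lists (−0.15, 0.77, up). With CCl4 at day 84 it held for pericentral (−0.094, 0.046, up), acute phase (−0.39, 0.15, down), stress (−0.13, 0.23, up) and pancreatic lists (−0.23, 0.045, up). Each of these medians was above 0 with spike-in scaling, from 0.063 (adipose) to 0.66 (stress, CCl4 at day 28).

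Other lists not called above were called in some alternatives. With only the groups compared, P450 enzymes (DEN at both days, CCl4 at day 84) and bile acid genes (DEN at day 28, CCl4 at day 84) were called lower, and stellate markers (DEN at both days) and macrophage and endothelial markers (DEN at day 28) higher. With no filter on dim probes, stellate, preneoplastic, macrophage and endothelial markers were called higher with DEN at day 28. Endothelial markers were so with normexp, they and preneoplastic markers with the all-array filter, and both and macrophage markers with all probes. Without control 1 stellate and endothelial (adjusted p = 0.0295 and 0.0437), without control 2 preneoplastic (adjusted p = 0.0313), without control 3 macrophage (adjusted p = 0.0042) and without DEN 1 endothelial markers (adjusted p = 0.0473) were called then. P450 enzymes were called lower with DEN at day 84 without DEN 3 (adjusted p = 0.0386). The followed-up genes were called lower with DEN at day 84 with no filter on dim probes. Spike-in scaling called 20 uncalled list results in the direction of their test, all lower.

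Shared calls compare the effects of days and compounds. The DEN effects of both days shared 1107 genes in the same direction (545 higher, 184 expected, and 562 lower, 244 expected), 67.5% of the calls of day 28, and 35 were opposite. The CCl4 effects of both days shared 5223 (2260 higher, 796 expected, and 2963 lower, 1332 expected), 80.2% of those of day 28, with 64 opposite. Within day 28 the compounds shared 1307 genes (658 higher, 223 expected, and 649 lower, 264 expected), and 37 were opposite. Within day 84 they shared 4472 (1778 higher, 658 expected, and 2694 lower, 1233 expected), and 103 were opposite. Across genes, the effects correlated at 0.52 between days for DEN and 0.85 for CCl4, and at 0.62 and 0.74 between compounds at day 28 and day 84. Effects against the same controls correlate at 0.50 in 20 simulations of unchanged groups. These give almost no calls, so 0 shared calls were fixed in advance. The covariance above the simulated one was 0.23 for DEN and 0.97 for CCl4 across days, and 0.27 and 0.75 within day 28 and day 84. Part of the excess within a day can come from the shared controls, since 3 controls cannot be split into groups of 2.

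The DEN effect differed between days in 1752 genes, 834 higher at day 84 and 918 lower. Of the CCl4 effects, 658 differed, 383 higher and 275 lower. The DEN effect on NRF2 targets was larger at day 84: 20 of 28 members were higher and 0 lower. Their median was 1.103 (camera adjusted p = 9.79e-20 and 0.0235 estimated). On preneoplastic markers it was larger too: 13 of 20 members were higher and 0 lower. Their median was 2.97 (camera adjusted p = 1.59e-17 and 0.0235 estimated). On the p53 list it was smaller: 1 of 23 members were higher and 7 lower. Their median was −0.37 (camera adjusted p = 0.0120 and 0.505 estimated). The CCl4 effect on cholesterol synthesis was higher at day 84: 15 of 23 members were higher and 0 lower. Their median was 1.07 (camera adjusted p = 1.61e-16 and 0.508 estimated). The CCl4 effects were in part measured across slides, and with slide as a block 1969 and 402 genes differed. The share of higher genes was 47.6% and 58.2%, and 81.5% and 21.4% with spike-in scaling, where 744 differed for DEN.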

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

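The tests of spike-in signal, slide, a larger response of 1 rat, hepatocyte share and scaling to the 75th percentile were chosen after their results were seen, as was scaling to the spike-in probes.

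The results of this and the next paragraph stand out because the effect of a compound differed between day 28 and day 84 by the interaction test of limma. Several of these genes were not well above background in some groups, so their fitted differences are no bounds. With DEN 1752 genes differed. The effect was lower at day 84 for Plppr1 (−4.56), Mmd2 (−4.51), Casr (−4.10), Aox3 (−3.58) and Slc25a30 (−3.19), and higher for Slc7a11 (9.67), Ugt2b7 (8.95), Bex1 (8.92), Defb1 (8.72) and Pcp4 (8.38). The call was lost for Plppr1 without DEN 2 of day 84 (−4.17), for Mmd2 without any array but control 3 of either day (−4.89 to −3.58), for Aox3 without any but DEN 1 and 3 of day 84 (−3.83 to −2.75) and for Casr without any but these 4 (−4.37 to −3.08). List medians of the difference were −0.37 for p53 targets, 1.29 for cell cycle, 1.103 for NRF2 targets, 2.97 for preneoplastic markers, −0.98 for pericentral and −0.39 for periportal markers, −0.34 for hepatocyte secretory genes, −0.54 for PPARalpha targets, −0.39 for interferon-stimulated genes, −0.44 for acute phase proteins, −0.49 for lymphocyte, 1.30 for cholangiocyte and 3.20 for adipose markers. With an estimated correlation the NRF2 and preneoplastic lists kept their calls (adjusted p = 0.0235 for each).

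With CCl4 658 genes differed between days. The effect was lower at day 84 for Slc25a30 (−3.34), Cyp4a2 (−3.20), Fut1 (−3.02), Ccnf (−2.90), Colq (−2.74) and Cdh17 (−2.05), and higher for Akr1b7 (5.997), Sult2a2 (5.23), Bex1 (4.59), Aard (4.11), Clec10a (3.87) and Nfia (0.62). The call was lost for Colq without any 1 array (−2.94 to −2.46) and for Slc25a30 without control 2 or CCl4 1 of day 84 (−3.24 to −2.98). It was lost for Cyp4a2 without control 1 or CCl4 1 or 3 of day 28 or control 1 or 2 of day 84 (−3.21 to −2.85), and for Cdh17 without CCl4 3 of day 28 or control 1 or 2 or CCl4 1 or 2 of day 84 (−2.04 to −1.84). For Nfia this held without control 2 or 3 or CCl4 3 of day 28 or control 1 or 2 or CCl4 2 of day 84 (0.51 to 0.64). List medians of the difference were −0.31 for cell cycle, 0.71 for matrix, 0.98 for preneoplastic markers, 0.34 for hepatocyte secretory genes, 1.07 for cholesterol synthesis, −0.37 for PPARalpha targets, 0.36 for acute phase proteins, 0.58 for erythroid markers and 0.73 for female-predominant genes, none called with an estimated correlation (adjusted p = 0.508 to 0.728).

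Other splits of the same arrays were counted. For the 6 comparisons of 2 groups, 3 against 3 arrays give 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, gave as many genes: 1639, 6514 and 4918 at day 28 against at most 0, 1 and 0 in other splits, and 5750, 7013 and 3743 at day 84 against at most 0, 1 and 0. Of 100 splits within days, 5 gave as many genes as the 1752 that differed between days for DEN (highest other 3866). For CCl4 10 gave as many as the 658 (highest other 5876). All but the real split (4 and 9) kept a group, and so the treatment, whole. With every group broken at most 0 genes differed, so these splits cannot decide on chance. For calls shared by both days, 1 of 100 splits, the real one, gave as many. This held for DEN (1107, highest other 0) and CCl4 (5223, 0). It also held for calls shared at day 84 (4472, 2453) and genes lowered by CCl4 alone (2032, 649). For calls shared at day 28 (1307) it was 2 of 100, and a split that kept a group whole shared 4345. Splits that broke every group gave at most 1 shared call and at most 0 genes lowered by CCl4 alone. Mixed groups leave almost no calls, so these low counts were fixed in advance. Whether the sharing itself exceeds chance is not tested by these splits.

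The 75th percentile of array signal over the spike-in probes was higher in all 4 treated groups than in controls. Spike-in signal argues against itself as the source, since it differed by at most −0.0427 (log2) between treated and control groups, and slide does as well, since the smallest rise within a slide was 0.379. A smaller share of signal in the most abundant transcripts went with the rise: the summed signal rose by at most 0.488 of the rise of the percentile, and the 100 brightest probes held 18.7% of signal in controls, 16.8% with DEN and 14.2% with CCl4 at day 28, and 17.7%, 14.0% and 15.0% at day 84. Whether total mRNA per amount of RNA also differed stays open, as does the response to treatment itself.

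Replicate 2 of CCl4 at day 28 lay apart on the first principal component (75.7 against 38.1 and 25.4). Its deviation from the other 2 arrays correlated across genes with the CCl4 effect at day 84 at 0.727, and 5911 of the 7013 genes called then (84.3%) deviated in that direction, so a larger response to CCl4 in that rat may account for it. A technical difference that depends on signal stays open, with a correlation with mean level of −0.284. Genes are not independent replicates, and 1 rat cannot separate its response from its sample.

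Hepatocyte secretory genes were lower with CCl4 at day 28 (27 of 27). A lower hepatocyte share would lower all 27 alike only if loss were even and no other cell expressed them. The changes spread 3.88 times their SE, −2.96 to −0.38, which argues against that case only. The gap of 1.58 between stellate and sinusoidal endothelial medians does not test this. Scaling to the 75th percentile could account for part. With spike-in scaling 14 of the 27 were still lower and 1 was higher, with a list median of −0.32 against 0.71 for all genes. Uneven loss and the response of hepatocytes to CCl4 stay open and were not tested.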

How the results depend on the processing

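Spike-in scaling and leaving out the third slide were chosen after the data were seen. A direction counts as turned where the gene or list was called in the fit or the alternative, while uncalled lists changed sign in several settings. Directions were kept under all alternatives but 3. With normexp, Cd3e with DEN at day 84 turned to −0.30. With quantile normalization, Fgb (DEN, day 28) turned to 0.0061, Apoa1 (CCl4, day 28) to 0.047, Serpina1 and Apoa1 (DEN, day 84) to 0.019 and 0.36, and Fga and Fgb (CCl4, day 84) to 0.060 and 0.13. With spike-in scaling, at day 28 with DEN, Fgb turned to 0.012 and Ldlrad4 to 0.035. At day 28 with CCl4 it turned Cdkn1a to 0.16, Gclc to 0.67, Glul to 0.57, Apoa1 to 0.39, Apob to 0.18, Sqle to 0.024, Acacb to 0.064, Stat2 to 0.0019, Oas1b to 0.15, Ifit2 to 0.67, Fga to 0.029, Atf4 to 0.16, Dnase1l3 to 0.026, Ehd3 to 0.067 and Lyve1 to 0.50. At day 84 with DEN it turned Cdkn1a to 0.014, Apoa1 to 0.55, Apob to 0.028, Cyp27a1 to 0.17, Oas1b to 0.11, Dnase1l3 to 0.078, Pecam1 to 0.28, Ldlrad4 to 0.15 and Nfia to 0.21. The test of the female-predominant list turned from up to down at an unchanged shift of −0.81. At day 84 with CCl4 it turned Apoa1 to 0.39, Cyp27a1 to 0.17, Fga to 0.13, Fgb to 0.061 and Lyve1 to 0.22. Spike-in scaling adds 1 constant per comparison to all genes, which by itself turns small falls; for the other settings the cause was not tested.

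Counts moved by over 1.5 times as follows. Spike-in scaling gave 3906 genes for DEN at day 28, 2378 for CCl4 against DEN at day 84, 744 for the DEN difference between days, 393 lowered by CCl4 alone, 3160 DEN calls shared by both days and 3618 calls shared by both compounds at day 28. The CCl4 difference between days gave 1163 with normexp, 397 with no filter on dim probes, 402 with slide as a fixed block, 255 on one slide and 369 with only the groups compared. CCl4 against DEN at day 84 gave 2012 with slide as a fixed block and 1812 on one slide. With only the groups compared, 1701 DEN calls were shared by both days and 572 calls by both compounds at day 28. The cause was not tested, except that these 2 slide settings and the last leave fewer arrays or degrees of freedom. Testing all probes, which counts more features, gave 4025, 18554 and 13703 at day 28 (DEN, CCl4, CCl4 against DEN), 15796, 19727 and 9076 at day 84, 3897 and 1382 for the DEN and CCl4 differences between days, 5712 lowered by CCl4 alone, and 2726, 14317, 3152 and 12254 shared (DEN days, CCl4 days, day 28, day 84). Requiring a 2-fold change, which can only lower a count, gave 368, 2064, 1351, 1493, 2402, 1102, 700, 321, 375, 216, 1583, 255 and 1150 in the same order.

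Leaving out 1 array at a time gave 700 to 1319 genes for DEN at day 28, 5581 to 6597 for CCl4 at day 28, 3775 to 5234 for CCl4 against DEN at day 28, 4593 to 5506 for DEN at day 84, 6352 to 6607 for CCl4 at day 84, 2770 to 3246 for CCl4 against DEN at day 84, 874 to 2130 and 382 to 1360 for the DEN and CCl4 differences between days, 1339 to 2078 lowered by CCl4 alone, and 502 to 1055, 4623 to 5390, 570 to 1811 and 3708 to 4322 shared (DEN days, CCl4 days, day 28, day 84). Single arrays moved these by over 1.5 times. Without control day 28 replicate 2, DEN at day 28 gave 1023 and 840 calls were shared at day 28. Without DEN day 28 replicate 1 these were 700 and 570, with 502 shared DEN calls, without replicate 2 1019 and 822, with 718, and without replicate 3 1006 and 840, with 726 and a DEN difference between days of 1154. That difference was 1112 and 1037 without control day 84 replicates 1 and 2 and 874 without DEN day 84 replicate 2. The CCl4 difference was 1360 without CCl4 day 28 replicate 2, which left 1339 genes lowered by CCl4 alone, 403 and 382 without control day 84 replicates 1 and 2 and 386 without CCl4 day 84 replicate 1.

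The replicate block gave 1557 and 6471 genes (DEN and CCl4, day 28), 5683 and 6978 (day 84), and no count moved by over 1.5 times. Replicate numbers do not pair the rats: the median correlation of 45 pairs with the same number was −0.00425, and 9 of 18 arrays correlated best with their own number. Slide as a random block has no list values, since camera takes no random block. The authors' value table, eBayes with a trend, the all-array filter, median scaling and the random slide block moved no count by over 1.5 times. Among named genes, 91 lost their call with spike-in scaling, 28 with normexp, 28 with quantile normalization, 27 with slide as a fixed block and 24 with no filter on dim probes, each in the same direction. Of list calls against control, an estimated correlation lost 43 (all but p53, DEN, day 28), spike-in scaling 8 and quantile normalization 6. Folds of genes dim in 1 group are bounds.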

Other observations

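Genes that differ between male and female rat liver changed with CCl4. The test of a loss of the male pattern was chosen after the result was seen. Of male-predominant genes at day 84 with CCl4, 1 of 12 members rose and 10 fell (1 and 10 alone). Their median was −1.44 (camera adjusted p = 0.0146 and 0.712 estimated), a call lost with only probes well above background on all arrays, and Obp3 (−6.72 ± 1.16), an odorant-binding protein made in male liver, fell with Cyp2c11. At day 28 the list was not called with CCl4 (1 rose and 9 fell of 12, 2 and 10 over the list alone, adjusted p = 0.100). It was called without replicate 3 of CCl4, to which slide as a block amounts, with a shift of −1.82 (−1.53 unblocked) that rests on replicate 1 and on replicate 2, which stands apart. With DEN it was not called at day 28 (1 rose and 0 fell of 12, adjusted p = 0.793) or day 84 (1 rose and 7 fell of 12, adjusted p = 0.163), and it was called lower at both days with only the groups compared. Against DEN the male list was lower with CCl4 at day 28 (median −1.12, camera adjusted p = 0.0325 and 0.672 estimated) and day 84 (median −0.58, camera adjusted p = 0.0233 and 0.654 estimated). Of female-predominant genes, Cyp2c12, a P450 of female rat liver, rose with DEN and CCl4 at day 28 (1.85 ± 0.16 and 2.79 ± 0.16) and day 84 (3.60 ± 0.16 and 3.08 ± 0.16). The female-predominant list was not called with DEN (1 rose and 0 fell of 12, adjusted p = 0.558, median −0.26 and mean 0.22 with the test pointing up) and CCl4 (2 rose and 6 fell of 12, adjusted p = 0.578) at day 28 and with DEN (5 rose and 6 fell of 12, 5 and 7 over the list alone, adjusted p = 0.744, median −0.89 and mean 0.42 with the test pointing up) and CCl4 (5 rose and 5 fell of 12, adjusted p = 0.578, median −0.46 and mean 0.95 with the test pointing up) at day 84. With spike-in scaling the medians of −0.26 and −0.46 were 0.12 and 0.051.

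A loss of the male pattern of liver gene expression may underlie the fall with CCl4 at day 84. If so, female-predominant genes would rise as a list, and their camera adjusted p was 0.578 with 5 higher and 5 lower, which leaves the hypothesis undecided.

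Regulators of DNA methylation and chromatin had no called shift with DEN (2 rose and 1 fell of 20, adjusted p = 0.664) and CCl4 (5 rose and 5 fell of 20, adjusted p = 0.938, median 0.035 and mean −0.17 with the test pointing up) at day 28, and DEN (4 rose and 6 fell of 20, adjusted p = 0.793) and CCl4 (3 rose and 9 fell of 20, adjusted p = 0.584) at day 84. Of the members, Gnmt, which methylates glycine with S-adenosylmethionine, was called lower in all 4 treated groups (with DEN at day 28 not without any 1 of the 6 arrays, at −1.17 to −0.88), −1.03 ± 0.32 and −2.83 ± 0.32 at day 28 and −1.40 ± 0.32 and −2.05 ± 0.32 at day 84 for DEN and CCl4. Ahcy, which clears the product S-adenosylhomocysteine, fell with CCl4 (−1.44 ± 0.17 and −1.20 ± 0.17).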
